A study of Mus musculus with 6 samples.

How the data were processed

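RNA was sequenced from green fluorescent cells of the mouse hippocampus. The animals carried a tamoxifen-inducible Cre under the Nestin promoter and a membrane GFP reporter at Rosa26, a design that marks neural progenitor cells and their progeny. GFP-positive cells were collected by magnetic sorting, and each of the 6 samples came from a different animal. Per the labels' protocols, lysates were kept in TRIzol, RNA was purified on columns and libraries were made with an NEB RNA kit. All animals received cuprizone, a copper chelator that causes demyelination, for 10 weeks, followed by 4 weeks of recovery. The 3 vehicle animals received 0.1% bovine serum albumin in saline, and the 3 treated animals received neuregulin 1 beta 1 (Nrg-1β1) at 60 µg per kg per day. This unit is that of the series description, while the sample labels give the same dose in grams, so the dose is uncertain.

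The submitters' processing notes name Trimmomatic and Bowtie2. Their versions, the genome build, the read counter, the strand setting, the normalization and the gene filter are not given in the sources used here, so no coordinates are printed. The deposited values are on a log2 scale, and the table has 27102 genes. In 6779 of them all libraries are blank, and the other 20323 were analysed. The lowest value of each library equals the log2 of 4. After 4 was subtracted from the unlogged values, every value was a whole multiple of a single step per library, within 0.02 of a read for 100% of values and with a largest deviation of 0.01. The deposited values were therefore read as log2(normalized count + 4), with whole reads divided by a factor per library. This reading comes from the values, not from a stated method. Every analysed gene reached at least 0.507 CPM in at least 1 library.

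A symbol was missing for 1917 analysed genes, which carry only a number. Of these, 980 were named by gene number from the RefSeq annotation of GRCm38.p6, used for names only, and 937 stayed unnamed. For 4 genes that share a symbol with another, the gene number was added to the symbol. Ribosomal protein genes and predicted genes have many near-identical copies, so the authors' counting could have split their reads, and antisense or overlapping genes could not be told apart without a strand setting.

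The recovered reads gave the depth of each library, from 567073 to 72953034 reads. At the lowest depth a single read equals 5.17 normalized counts, and at the highest 0.0605. Intervals are 95%, exact Clopper-Pearson on the reads pooled within a group, scaled by the libraries' steps. Floors are 3 reads over a group with none. Both cover counting error only and leave out the spread between animals, because the reads of a group are pooled. The reads carry no molecular identifiers, so copies of the same molecule could not be told apart either.

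The main comparison, fixed before the data were examined, was limma with an intensity trend on the log2 values as deposited, with group as the only term, all 20323 genes and Benjamini-Hochberg adjustment at 0.05 (R 4.3.3, limma 3.58.1). All adjusted p-values come from limma. Log2 differences are Nrg-1β1 minus vehicle on the log2(normalized count + 4) scale, which understates changes of genes with few reads. The count models planned for count tables were not used because the deposited unit is log2. The 41 gene lists, also fixed beforehand, hold 795 distinct genes, of which 775 had a value. They were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run beside it. List scores are the mean over members of the log2 value after each gene was centred on its mean over the 6 libraries.

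Genes were named by a rule fixed beforehand. Its first part takes the 10 largest differences in each direction among genes past the threshold whose groups do not overlap and whose mean in the higher group is at least the median over genes, here 4.49. Its second part takes up to 4 members with the smallest p of each list with a changed member or past its set test. Once the files had been seen, this was set to 4 where a member changed and 2 where only the set test passed. Its last part is a fixed set of lineage and receptor genes. Xist met the rule, while Ddx3y, Kdm5d, Uty, Eif2s3y and Bc1 were added after their values were seen. A few genes that the rule names are not reported here.

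On simulated counts for the 20323 genes at these depths, with 200 genes changed in the Nrg-1β1 against vehicle comparison, the test recovered 7.46% of 2-fold, 74.6% of 4-fold and 90.9% of 8-fold changes, with 5 false calls. With no gene changed it called 0 genes, while 1214 lay under an unadjusted p of 0.05, and 0 lists. The simulation drew genes independently of each other. Its changed genes all had a mean normalized count of at least 50, so recovery of genes with fewer reads was not simulated. All genes shared 1 dispersion (0.055), taken from genes with a mean of at least 200.

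Settings varied as fixed beforehand were a pseudocount of 0.1, quantile normalization, centring on library medians, limma without trend, a fold change of at least 1.5, a replicate block and leaving out each library. Settings chosen after seeing the data were pseudocounts of 1, 16 and 64, genes with a mean normalized count of at least 50, robust moderation, array weights, limma-voom on the recovered reads, reads thinned to 567073 per library in 11 draws, a term for the 2 deep libraries, removal of these, removal of the 2 vehicle libraries with few Y-linked reads, and removal of a loess trend with transcript length (the median over a gene's annotated GENCODE transcripts). For each higher gene with a length, the 20 genes nearest in log10 length and mean log2 value were compared with it. For a count of genes or lists, a change within 1.5 times was taken as the same. For genes and lists, a turned sign was counted where the main or the alternative value was past its threshold.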

Results

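The series compared GFP-positive progeny of Nestin-expressing hippocampal cells from 3 vehicle-treated and 3 Nrg-1β1-treated mice after 10 weeks of cuprizone and 4 weeks of recovery. The question set by the design is how Nrg-1β1, a ligand of the ErbB receptor tyrosine kinases, alters the transcripts of these cells after long demyelination. Depth differed strongly between libraries and partly with the group. The vehicle libraries held 72953034, 1075813 and 47076006 recovered reads, and the Nrg-1β1 libraries 567073, 662909 and 1327003. At least 10 reads were found for 16906, 8670 and 16860 genes in the vehicle libraries and for 6480, 6580 and 8388 genes in the Nrg-1β1 libraries.

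**Figure D1:**
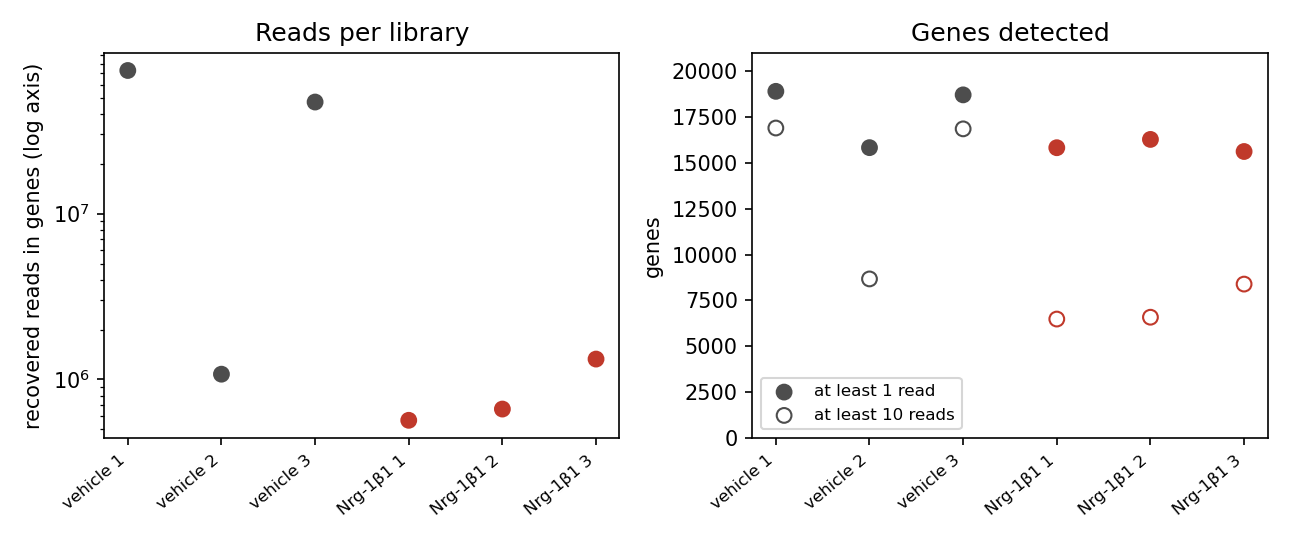
Recovered reads per library on a log axis (left) and number of genes with at least 1 read or at least 10 reads (right), with vehicle libraries in grey and Nrg-1β1 libraries in red. Vehicle libraries 1 and 3 hold 72953034 and 47076006 reads, and the other 4 hold between 567073 and 1327003.

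Between Nrg-1β1 and vehicle, 127 genes were lower and 89 were higher at an adjusted p of 0.05 (limma). The lower genes included markers of blood vessels, choroid plexus and microglia, immediate early genes and inducible heat shock genes. The higher genes included ribosomal protein and mitochondrial genes, the neural transcription factor gene Sox1 and the glutamate receptor gene Gria1. The median difference over all genes was 0.03 on the log2 scale. The groups did not overlap for all 216 changed genes and for 17.7% of all genes, where chance gives 10%. The count was not stable. It was 0 when any Nrg-1β1 library or vehicle library 2 was left out, 56 without vehicle library 1 and 4 without vehicle library 3, and it was 0 in each of 11 draws thinned to 567073 reads per library, while 2644 genes lay under an unadjusted p of 0.05 with all libraries as deposited and a median of 1317 after thinning. Thinning made only the read totals equal, and in a thinned draw 13535 to 15831 genes per library still had a read. With quantile normalization 12 genes were higher and 53 lower, and with centring on library medians, which moved the median difference to 0.25, 335 were higher and 164 lower.

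The largest decrease was in Ttr, which encodes transthyretin, the thyroid hormone carrier made by the choroid plexus. Its log2 value was 11.46 ± 1.02 in vehicle and 6.61 ± 0.58 in Nrg-1β1 (SD, n = 3 each), a difference of -4.85 ± 0.41 (SE, adjusted p = 1.01e-05, limma). The inducible Hsp70 genes Hspa1a and Hspa1b differed by -3.71 and -4.29 (adjusted p = 8.74e-05 and 0.000134). The transcription factor gene Klf4 differed by -4.32, and Vtn, which encodes vitronectin, by -3.89. The endothelial genes Ly6a, Ly6c1 and Slco1a4 differed by -3.66, -3.59 and -3.62, and Slc22a8, an organic anion transporter gene, by -3.49. Several of these had almost no reads in the Nrg-1β1 libraries, where 51 of the 127 lower genes had fewer than 10 reads in total. Vtn had 3 reads there, and its pooled vehicle level was 27.8 times higher (95% counting interval 9.50 to 135). Slc22a8 had 1 read, with a ratio of 49.2 (8.82 to 1944). Xist, the RNA that coats the inactive X chromosome, differed by -4.06 (adjusted p = 0.00356).

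Sex-linked transcripts differed between the libraries within the vehicle group. Xist had 3255, 216 and 1045 reads in vehicle libraries 1 to 3 and 2, 3 and 1 reads in the Nrg-1β1 libraries. The Y-linked Ddx3y had 82, 1 and 1994 reads in the vehicle libraries, against 29, 22 and 15 in the far shallower Nrg-1β1 libraries. Kdm5d had 17, 1 and 558 reads in vehicle and 16, 16 and 8 in Nrg-1β1. Uty had 1, 0 and 395 reads in the vehicle libraries, and Eif2s3y had 43, 0 and 816. Vehicle library 3 thus held both kinds of transcript, with Xist at a log2 value of 6.07 against 3.84, 4.27 and 2.82 in the Nrg-1β1 libraries. Without vehicle libraries 1 and 2, where Y-linked reads were few, vehicle library 3 alone remained in its group, so no gene count is given. All 216 changed genes kept the sign of their difference there, which was fixed in advance because their groups did not overlap.

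Endothelial genes were lower as a group. Of 18 measured members 11 fell, 0 rose and 7 did not pass, and adjusted over the list alone 18 fell. The median difference was -2.50 (camera adjusted p = 3.15e-21), and adjusted p = 0.178 with an estimated correlation. The tight junction gene Cldn5 went from 8.20 ± 1.31 to 4.72 ± 0.94 (SD, n = 3 each), and the efflux transporter gene Abcb1a differed by -3.08 (adjusted p = 0.00888, limma). The endothelial score was 0.97, 0.31 and 2.56 in the vehicle libraries and -1.30, -1.42 and -1.13 in the Nrg-1β1 libraries, so the shallow vehicle library 2 lay between. In the choroid plexus list 4 of 15 members fell, 12 adjusted over the list alone, with a median of -2.30 (camera adjusted p = 5.15e-14), and adjusted p = 0.178 with an estimated correlation. Besides Ttr these were Kl, which encodes Klotho (-3.44, adjusted p = 0.000731), and the potassium channel genes Kcnj13 and Kcne2. Kcne2 had 0 reads in the Nrg-1β1 libraries, which puts its pooled level at least 6.11-fold lower, and Kcnj13 had 1.

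Other vascular and barrier lists were also lower. The pericyte and smooth muscle list had 1 member that fell, Vtn, of 15 (median -1.25, camera adjusted p = 4.16e-06), and adjusted p = 0.214 with an estimated correlation. With the 4 members that had no read in a group placed at their bound, its median was -0.57. Its next members by p, Tagln (-1.90), Des (-1.33) and Myl9 (-1.82), did not pass. The meningeal and vascular fibroblast list (median -0.86, camera adjusted p = 2.50e-05) and the ependymal list (median -1.30, camera adjusted p = 5.02e-06) had 0 changed members, with adjusted p = 0.27 and 0.396 with an estimated correlation. Ogn and Igf2 differed by -2.06 and -1.34 in the first, and the cilia regulator gene Foxj1 and Tmem212 by -1.29 and -1.88 in the second, without passing. The ependymal score was -0.94 in vehicle library 2 and 1.15 and 1.75 in vehicle libraries 1 and 3, and its mean difference turned to 0.29 when these deep libraries were left out. In the erythroid list 4 of 10 members fell (camera adjusted p = 0.0163), and adjusted p = 0.396 with an estimated correlation. These were the globin genes Hba-a2 (-2.85), Hbb-bs (-2.75) and Hba-a1 (-2.62) and the heme synthesis gene Alas2 (-2.11). The erythroid list no longer passed without vehicle library 1 (adjusted p = 0.0646) or 2 (0.0712), or without Nrg-1β1 library 2 (0.11) or 3 (0.424).

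Microglial genes were lower. Of 21 members 10 fell and 11 did not pass, and adjusted over the list alone 18 fell. The median difference was -1.43 (camera adjusted p = 2.77e-15), and adjusted p = 0.192 with an estimated correlation. The purinergic receptor gene P2ry12 went from 9.10 ± 0.42 to 7.07 ± 0.58 (SD, n = 3 each, adjusted p = 0.00477, limma), and Siglech, Fcrls and the protease gene Ctss differed by -1.66, -1.61 and -1.67. The fractalkine receptor gene Cx3cr1 fell by 1.21 ± 0.28 (SE, adjusted p = 0.0448, limma), while Aif1 differed by -2.27 ± 0.60 (SE) without passing (adjusted p = 0.0708, limma). In the complement and phagocytosis list 3 of 19 members fell, among them the integrin gene Itgam (-1.44) and C1qc (-1.58), while C1qa differed by -1.45 and missed the threshold (adjusted p = 0.051, limma). Its median was -0.81 (camera adjusted p = 4.92e-06), and adjusted p = 0.178 with an estimated correlation. The border-associated macrophage list (median -0.76, camera adjusted p = 1.76e-05) and the disease-associated microglia list (median -0.36, camera adjusted p = 0.0301) had 0 changed members, with adjusted p = 0.178 and 0.5 with an estimated correlation. Stab1 (-1.40) and Mrc1 (-2.05) were the members of the first with the smallest p, and Trem2 (-1.23) and Lyz2 (-1.24) those of the second. The second no longer passed without vehicle library 1 (adjusted p = 0.0872) or 2 (0.556), or without Nrg-1β1 library 1 (0.17). Its mean difference turned to 0.14 without vehicle libraries 1 and 2, which leaves vehicle library 3 alone.

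Immune and stress lists shifted the same way. Of 18 members of the antigen presentation list 0 passed and 7 fell adjusted over the list alone (median -1.01, camera adjusted p = 2.08e-07), with H2-T23 at -1.51 and H2-K1 at -1.14. In the cytokine and chemokine list Ccl3 (-2.95) and Ccl4 (-2.67) fell of 23 members (camera adjusted p = 7.67e-07), while Tgfb1 (-1.27) and Il1a (-1.88) did not pass. In the interferon list Ifitm3 (-2.43) fell of 24 (camera adjusted p = 2.46e-06), and Trim30a, Eif2ak2 and Irf7 differed by -1.58, -1.40 and -1.68 without passing. In the reactive astrocyte list Hspb1 (-3.27) and Srgn (-2.05) fell of 24 (camera adjusted p = 7.67e-07), and Tm4sf1 (-2.19) and Emp1 (-2.04) missed the threshold. Each of these 4 lists had adjusted p = 0.178 with an estimated correlation. The reactive astrocyte list no longer passed among genes with a mean normalized count of at least 50 (camera adjusted p = 0.0603). With limma-voom on the recovered reads of those genes it did not pass either (0.149, and 0.23 with library totals). In the heat shock list 3 of 14 members fell, Hspa1a, Hspa1b and Hspb1, and Hsph1 differed by -0.43 (list median -0.31, camera adjusted p = 0.00101), with adjusted p = 0.249 with an estimated correlation. With read depth class as a term, where the difference rests on vehicle library 2, the list median was 0.09 and the mean -0.64.

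Immediate early genes, which are transcribed within minutes of a stimulus, were lower. Of 20 members 12 fell, and adjusted over the list alone 17 fell and 1 rose. The median was -1.86 (camera adjusted p = 4.94e-17), and adjusted p = 0.178 with an estimated correlation. Fos went from 8.99 ± 0.36 to 5.78 ± 1.33 (SD, n = 3 each, adjusted p = 0.00324, limma), and the mRNA decay factor gene Zfp36 and the transcription factor gene Klf2 differed by -2.90 and -2.98. The score was 0.81, 0.80 and 1.14 in the vehicle libraries and -1.42, -0.80 and -0.54 in the Nrg-1β1 libraries. In the MAPK feedback list, which did not pass (camera adjusted p = 0.915) and whose median (0.09) and mean (-0.11) differ in sign, Ier3 (-3.24) and Egr1 (-1.57) fell of 15 members. Ier3 had 3 reads in the Nrg-1β1 libraries and a pooled ratio of 14.2 (4.85 to 68.9). Spry2 and Spred2 differed by 1.09 and 1.21 without passing. In the BMP and TGF-β list the receptor genes Tgfbr2 (-1.46) and Tgfbr1 (-1.40) and the target gene Id1 (-1.92) fell of 21 (camera adjusted p = 0.0404), with adjusted p = 0.461 with an estimated correlation. The list no longer passed without vehicle library 2 (adjusted p = 0.0627) or 3 (0.162), or without Nrg-1β1 library 1 (0.0633) or 3 (0.33).

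**Figure D2:**
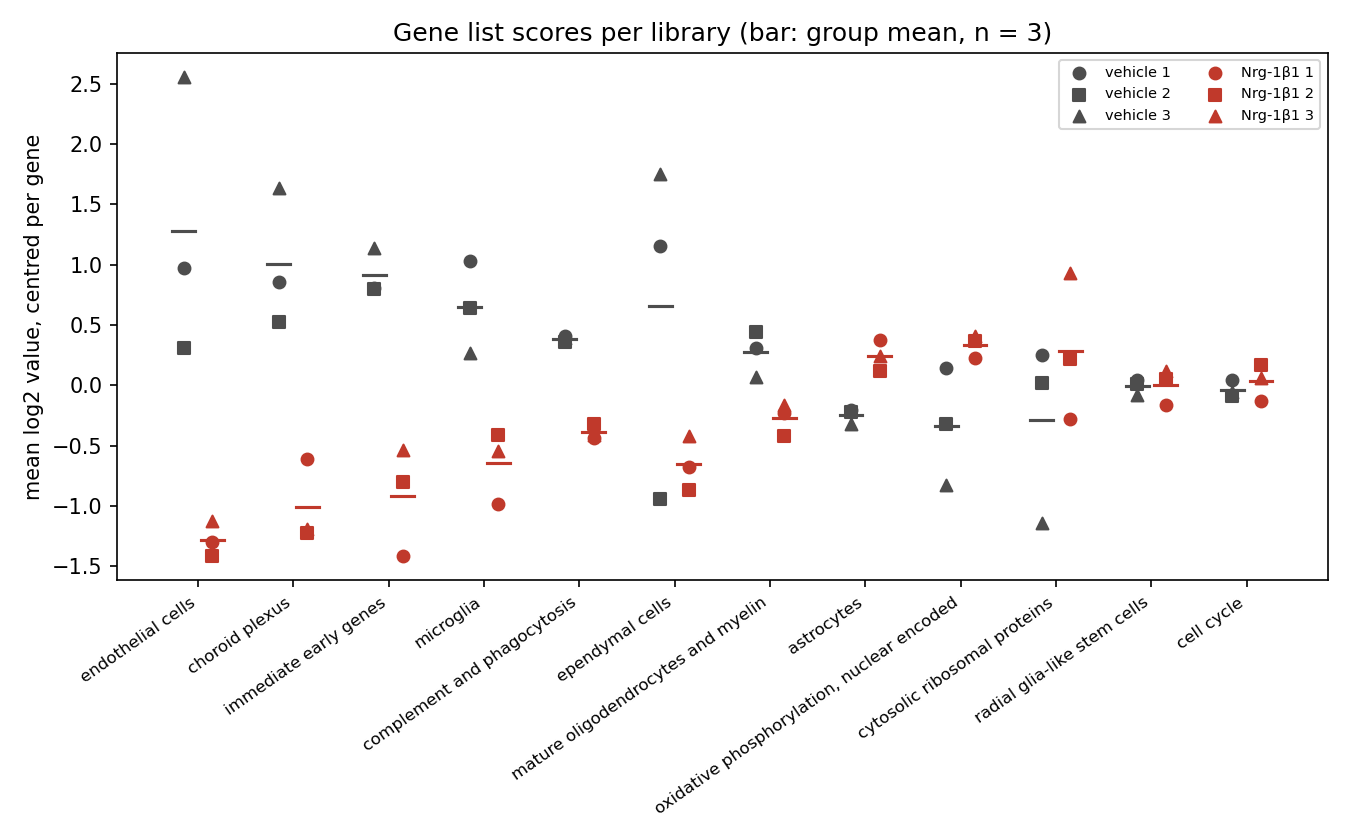
Score of 12 gene lists in each library, as the mean log2 value of the members after each gene was centred on its mean over the libraries, with vehicle in grey, Nrg-1β1 in red, a symbol per library and a bar at each group mean (n = 3). The endothelial scores lie between 0.31 and 2.56 in vehicle and between -1.42 and -1.13 in Nrg-1β1, and the ependymal score of vehicle library 2 (-0.94) lies with the Nrg-1β1 libraries.

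Genes of the neural progenitor and neuroblast lineage did not pass as groups. The median was 0.07 in the radial glia-like stem cell list (camera adjusted p = 0.711), 0.40 in the intermediate progenitor and neuroblast list (0.198), where 12 of 18 members had a positive difference, and 0.14 in the cell cycle list (0.583). In the stem cell list 1 of 19 members rose, Sox1, from 7.29 ± 0.93 to 9.26 ± 0.51 (SD, n = 3 each, adjusted p = 0.0194, limma). Nes, which encodes the intermediate filament nestin, differed by -1.65 ± 0.42 (SE) and missed the threshold (adjusted p = 0.0582, limma). Vim and Prom1 differed by -1.41 and -1.58 without passing. Sox2 differed by 0.47 ± 0.30 (SE), Eomes by -0.93 ± 0.52, Neurod1 by -0.92 ± 0.51, Dcx by 1.23 ± 0.63 and Prox1 by 0.11 ± 0.46, none past the threshold. The proliferation gene Mki67 had 90, 0 and 80 reads in the vehicle libraries and 0, 1 and 2 in the Nrg-1β1 libraries, so a difference was not detectable at this depth.

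In the neuronal lists, the synapse list was higher (median 0.34, camera adjusted p = 0.00158), and adjusted p = 0.396 with an estimated correlation. Of its 26 members 1 rose, the AMPA receptor gene Gria1, from 9.04 ± 0.31 to 10.47 ± 0.45 (SD, n = 3 each, adjusted p = 0.0286, limma), and Snap25, Homer1 and Shank3 differed by 0.98, 0.94 and 0.91 without passing. The neuron list shifted by a median of 0.18 (camera adjusted p = 0.0328) with 0 changed members, and adjusted p = 0.526 with an estimated correlation. Slc17a7 and Nrgn differed by 1.16 and 1.11 in it, and Rbfox3 by 0.12 ± 0.34 (SE), without passing. The neuron list no longer passed without vehicle library 3 (adjusted p = 0.407) or without Nrg-1β1 library 2 (0.0853) or 3 (0.216). With read depth class as a term, where the difference rests on vehicle library 2, the synapse median was 0.18.

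In the oligodendrocyte lineage, the mature oligodendrocyte and myelin list was lower (median -0.58, camera adjusted p = 4.70e-05), with adjusted p = 0.214 with an estimated correlation. None of its 24 members passed over all genes, and 7 fell adjusted over the list alone. Gsn and Ugt8a differed by -1.20 and -1.08. Mog differed by -0.46 ± 0.29 (SE) and Mbp by -0.08 ± 1.03, without passing. The oligodendrocyte progenitor list did not pass (camera adjusted p = 0.147), and 1 of its 20 members rose, C1ql1 (1.99, adjusted p = 0.0382). Pdgfra differed by 0.90 ± 0.37, Olig2 by 0.39 ± 0.32, Sox10 by -0.27 ± 0.31, Tcf7l2 by 1.13, Olig1 by 1.11 and Enpp6 by -1.38, without passing. The cholesterol synthesis list was higher (median 0.38, camera adjusted p = 0.00855), with 0 of 23 members past the threshold and adjusted p = 0.353 with an estimated correlation. Insig1 and Dhcr7 differed by 1.16 and 1.24 in it. The cholesterol list no longer passed without vehicle library 2 (adjusted p = 0.0766) or without Nrg-1β1 library 3 (0.0505). Without the 2 vehicle libraries with few Y-linked reads, which leaves vehicle library 3 alone, the myelin median was -0.36.

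The astrocyte list was higher (median 0.58, camera adjusted p = 0.000198), with adjusted p = 0.206 with an estimated correlation and 0.0908 after quantile normalization. None of its 19 members passed over all genes, and adjusted over the list alone 5 rose and 1 fell. Sox9 differed by 1.06 and Slco1c1, a thyroid hormone transporter gene that brain endothelium also expresses, by -1.67. Gfap differed by 0.68 ± 0.34 (SE) and Aqp4 by 0.10 ± 0.33, without passing.

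The ErbB list did not pass (camera adjusted p = 0.586). Of its 26 members 1 rose, Lrig1, which encodes a negative regulator of ErbB receptors, from 8.32 ± 0.28 to 9.63 ± 0.38 (SD, n = 3 each, adjusted p = 0.0346, limma). Erbb2 differed by -0.14 ± 0.50 (SE), Erbb3 by -1.07 ± 0.56, Erbb4 by 0.78 ± 0.59 and Nrg1 by 0.54 ± 0.49, without passing. These 4 genes had at most 9 reads in any Nrg-1β1 library. Grb2, Adam17 and Akt2 differed by 1.19, -1.39 and 0.79 without passing. In the growth factor list, which did not pass (camera adjusted p = 0.402), Fgf1 (1.49) rose and Pdgfb (-2.15) fell, while Ntrk2 differed by 0.99. In the Notch list (0.586) Heyl (1.72) rose, while Dll4 (-2.05), Nrarp (0.98) and Jag2 (-1.27) did not pass. In the extracellular matrix list (0.402) Fn1 (-2.30) fell, while Col4a1 (-1.98), Sparc (1.40) and Thbs1 (-1.90) did not pass.

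The largest increases were in Rpl13a (3.52), Rps21 (3.31), Zrsr1 (3.16), Gm8618 (2.92), Rpl12 (2.84), Ndufa12 (2.76), Gm5075 (2.71), Gm5237 (2.67), Tomm6 (2.54) and an unnamed gene with the number 100628626 (3.31). Rpl13a, Rps21 and Rpl12 encode ribosomal proteins, Ndufa12 a subunit of respiratory complex I and Tomm6 a part of the mitochondrial import channel. Rpl13a went from 5.48 ± 2.14 to 9.01 ± 0.37 (SD, n = 3 each, adjusted p = 0.0116, limma), and the vehicle spread came from library 2, with a value of 7.94 against 4.54 and 3.97. In the ribosomal protein list 1 of 28 members rose, Rpl4 (1.65), and Rps14, Rpl11 and Rpl30 differed by 1.63, 1.76 and 1.30 without passing. The list's median was 0.55 (camera adjusted p = 0.000302), and adjusted p = 0.5 with an estimated correlation. Its score was 0.25, 0.02 and -1.14 in the vehicle libraries and -0.28, 0.22 and 0.93 in the Nrg-1β1 libraries, which overlap. The list no longer passed without vehicle library 3 (adjusted p = 0.187) or without Nrg-1β1 library 3 (0.429). Its median was 0.26 with read depth class as a term, where the difference rests on vehicle library 2.

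In the nuclear-encoded oxidative phosphorylation list Cox5a (1.90) and Atp5b (1.74) rose of 25 members (median 0.43, camera adjusted p = 0.000295), with adjusted p = 0.396 with an estimated correlation, while Atp5o (1.90) and Ndufa8 (3.21) did not pass. The mitochondrially encoded list was lower (median -0.69, camera adjusted p = 0.00322) with 0 of 13 members past the threshold, and adjusted p = 0.495 with an estimated correlation. In it mt-Nd3 differed by -1.23 and mt-Atp6 by -1.22. In the glycolysis list Ldhb (2.17) and Pfkl (1.30) rose of 21 members (median 0.47, camera adjusted p = 0.0119), with adjusted p = 0.396 with an estimated correlation, while the glucose transporter gene Slc2a1 (-1.55) and Pfkm (0.87) did not pass. The antioxidant list shifted by 0.32 (camera adjusted p = 0.0402) with 0 changed members, and adjusted p = 0.461 with an estimated correlation. Sod2 and Sod1 differed by 1.34 and 1.36 in it. The antioxidant list no longer passed without vehicle library 2 (adjusted p = 0.0506) or 3 (0.293) or Nrg-1β1 library 2 (0.0537) or 3 (0.484), the glycolysis list without vehicle library 3 (0.0904), and the mitochondrially encoded list without vehicle library 1 (0.18) or Nrg-1β1 library 3 (0.138). The Wnt (camera adjusted p = 0.73), lymphocyte (0.402), neutrophil (0.135), integrated stress response (0.373) and p53 (0.321) lists did not pass.

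**Figure D3:**
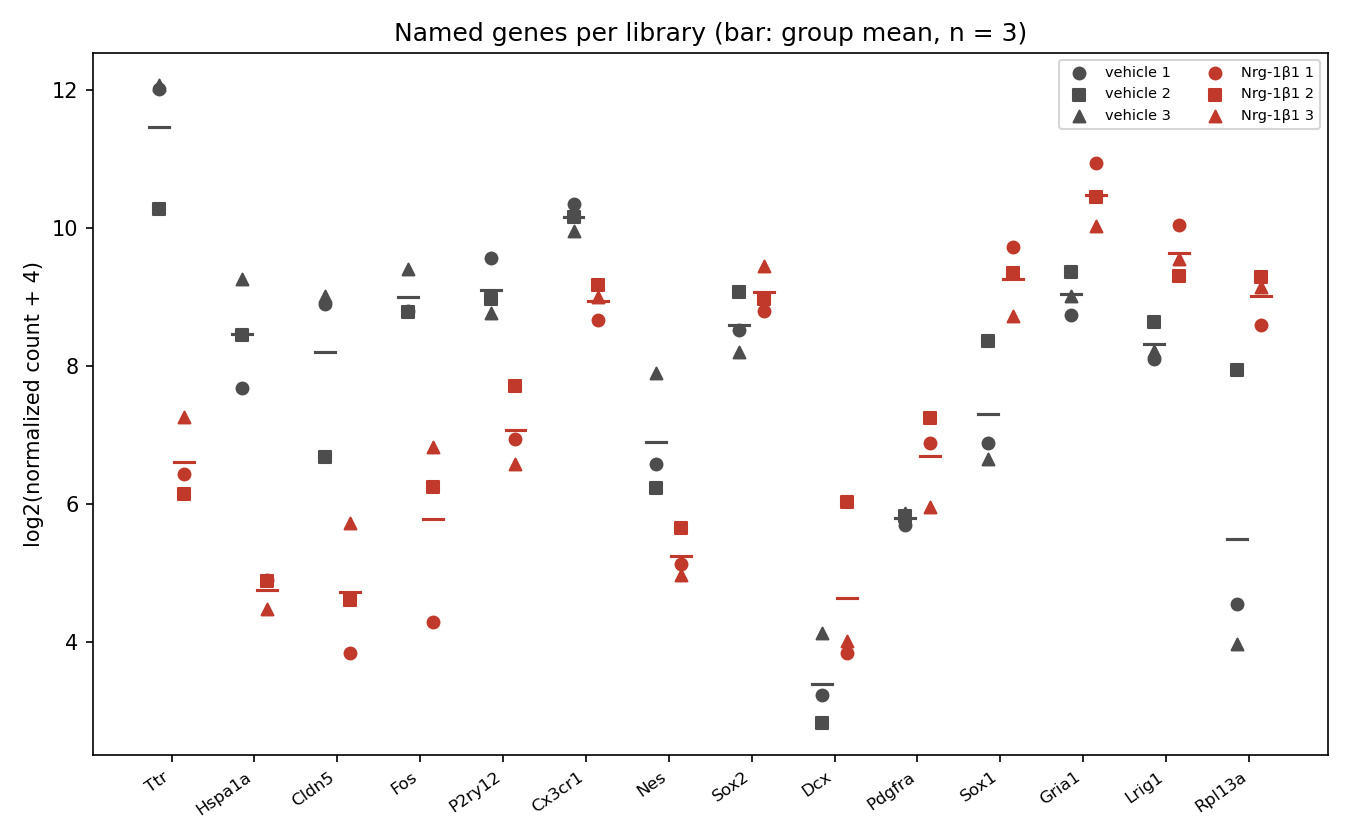
Log2(normalized count + 4) of 14 named genes in each library, with vehicle in grey, Nrg-1β1 in red, a symbol per library and a bar at each group mean (n = 3). Ttr lies near 11.46 in vehicle and 6.61 in Nrg-1β1, while Sox2 and Dcx overlap between the groups.

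In all, 27 of the 41 lists passed camera at its preset correlation, 19 lower and 8 higher, 0 passed with an estimated correlation (lowest adjusted p = 0.178) and 11 passed fry. Correlations between libraries across all genes were 0.941 to 0.965 within vehicle, 0.913 to 0.916 within Nrg-1β1 and 0.887 to 0.941 between groups. Over genes with a mean normalized count of at least 50 they were 0.862 to 0.885, 0.855 to 0.932 and 0.765 to 0.887, so pairs within and between groups overlapped. The first principal component held 36.6% of the variance and separated the groups, with vehicle library 2 at -25.5 and Nrg-1β1 library 3 at 9.01 nearest to each other. With read depth class as a term or without the 2 deep libraries, the difference rests on vehicle library 2, so only sizes are given. All 216 changed genes kept their sign, which was fixed in advance because their groups did not overlap, and 26 of the 27 lists did. The medians were -1.67 in the endothelial, -1.44 in the choroid plexus, -1.30 in the microglial and -1.75 in the immediate early list.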

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

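Pseudocounts of 1, 16 and 64, the filter at a mean of 50, robust moderation, array weights, limma-voom, thinning, the depth term, the 2 removals of vehicle pairs and the transcript length correction were chosen after seeing the data. As reported, 216 genes changed, 89 higher and 127 lower, and 27 lists shifted. The number of changed genes depended on the setting, from 0 to 627. All of the 216 that were tested kept their sign in each of the settings. Because their groups did not overlap, leaving out libraries, the depth term or another pseudocount could not have turned a sign. The changed, higher and lower counts were 10, 0 and 10 with a pseudocount of 0.1, 129, 49 and 80 with 1, 53, 20 and 33 with 64, 49, 11 and 38 for genes with a mean of at least 50, 65, 12 and 53 with quantile normalization, and 21, 2 and 19 without trend. They rose to 499 changed and 335 higher with median centring, 408, 174 and 234 with robust moderation, 334 changed and 151 higher with array weights, and 348 changed and 159 higher with the length trend removed. Of these, 201, 199, 208 and 210 were among the reported genes. limma-voom on recovered reads was run on the 6731 genes with a mean of at least 50, which held 170 of the 216. It gave 1 changed gene, higher, and 0 lower, with the deposited scaling or with library totals. Under an unadjusted p of 0.05 lay 1010 and 703 genes (limma-voom). The like count is the 49 of limma with that filter. The count was 0 in each direction with thinned reads. With the depth term and the 2 removals of vehicle pairs the group difference rests on 1 vehicle library, so no count is given. Leaving out single libraries gave 0 to 56 changed, 0 to 15 higher and 0 to 41 lower. The count was 56 without vehicle library 1, 0 without vehicle library 2, 4 without vehicle library 3 and 0 without any of the Nrg-1β1 libraries, where 2573 genes (without vehicle library 2) and 2270, 2337 and 3385 genes (without Nrg-1β1 libraries 1, 2 and 3) lay under an unadjusted p of 0.05. Fewer samples are part of this by construction; otherwise the cause was not tested.

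The number of lists fell to 15 and 16 with limma-voom under the deposited scaling and library totals, to 17 with the depth term, to 11 with fry and to 0 with an estimated correlation. The endothelial, microglial and immediate early lists passed in 24 of 24 settings at the preset correlation and the choroid plexus list in 21 of 21. With fry, however, the endothelial list did not pass (fry adjusted p = 0.0571). The microglial, immediate early and choroid plexus lists passed it narrowly (fry adjusted p = 0.0461 for each). The mean difference of the ependymal list turned to 0.29 with the depth term and without the 2 deep vehicle libraries. That of the disease-associated microglia list turned to 0.14 without the 2 vehicle libraries with few Y-linked reads. The cause of these turns was not tested. The comparison of single genes across settings covered only a part of the 20323 genes. In it 2455 values stayed the same, 942 lost the call, 99 gained it and 0 turned.

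With a replicate block 627 genes changed, 285 higher and 342 lower, and 27 lists shifted. The labels do not say whether the replicate numbers pair the animals. The deviations of same-numbered libraries correlated at -0.13, -0.0017 and -0.18, and no library correlated best with its own number. These values gave no sign of pairing, but with 3 libraries per group they do not settle it. The edgeR and DESeq2 alternatives planned for count tables, and edgeR on recovered reads, were not run because the deposited unit is log2. Depth limits genes with few reads in the 4 shallow libraries, where a single read moves a gene from 0 to 3.09 normalized counts in vehicle library 2 and to between 3.04 and 5.17 in Nrg-1β1.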

Other observations

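The tests of read depth, cell type share, preparation, genes matched on length and other splits were chosen after the result was seen, while those of sex and of the removed length trend were fixed before. The neuronal RNA Bc1, picked after its values were seen, took 1.74%, 8.25% and 0.279% of reads in the vehicle libraries and 0.515%, 1.93% and 21.4% in the Nrg-1β1 libraries. Transcripts of the mitochondrial genome took 47.4%, 28.3% and 31.3% in vehicle and 20.8%, 30.0% and 18.4% in Nrg-1β1.

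The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 216 changed genes and the highest other split 2, and the same highest value of 2 held for genes in a single direction, against 89 higher and 127 lower. In each of these counts 1 split, the real one, was as large. For lists the real split gave 27 and the highest other 18, so camera at its preset correlation passed many lists in splits that mix both treatments. The ribosomal protein list had a lower p in 4 of the other splits and the ependymal list in 3, while the endothelial, choroid plexus, microglial and immediate early lists had a lower p in 0. These last 4 lists have the smallest p in the real split, so this carries little weight. They also passed camera in 6, 6, 5 and 6 of the other splits, with lowest adjusted p = 8.03e-09, 1.38e-06, 4.97e-11 and 1.51e-06.

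The endothelial, choroid plexus, microglial and immediate early lists were lower in Nrg-1β1, and 3 explanations were tested. With every library thinned to 567073 reads, all 4 lists were still lower (highest adjusted p = 8.65e-09, for the choroid plexus list, which ranged from 2.27e-21 to 1.20e-05 over its settings), and the pooled median went from -1.85 to -1.78, which argues against the read total alone. The 9 lists of other cell types did not shift alike (permutation p = 0.0001, the smallest 9999 permutations can give). This p treats genes as independent, while the estimated correlation was 0.65 in the endothelial and 0.45 in the microglial list. The log2 scale also understates lists with few reads. The test therefore decides nothing, and a uniformly lower share of all other cells stays open. Sex cannot be told apart from the group: vehicle library 3, with Y-linked values like the Nrg-1β1 libraries, lay 2.14 above their mean over the 74 members, against a largest deviation of 0.25 of a single Nrg-1β1 library, which was set beforehand to count against sex, but it is a single library and its Xist value of 6.07 lay above their 2.82 to 4.27. Another preparation of the deep vehicle libraries stays open as well, because the shallow vehicle library 2, which lay 1.49 above the Nrg-1β1 mean and without them left list medians of -1.67, -1.44, -1.30 and -1.75, is a single library, and so do a change in single cell types carried through the sort and an effect of Nrg-1β1.

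For the genes higher in Nrg-1β1, 84 of the 89 had a transcript length, with a median of 905.5 bases against 1494.5 for all genes and 1806.2 for the lower genes. With each library's length trend removed 100% of the 84 passed, but the removal took only -0.05 to 0.01 from their differences, so it decides nothing, as does the same removal limited to genes with a mean of at least 50 (first run there with another smoother), where 60 of 77 passed and 16 without it. The 20 genes nearest to each in length and mean level had a median difference of 0.073 (median over the 84, SD 0.20, highest 0.57), against 1.76 for the higher genes (SD 0.50), which argues against a length effect shared by genes of the same length and level. Higher depth or another preparation of vehicle libraries 1 and 3 stays open, because vehicle library 2 is the single shallow vehicle library. With thinned reads the ribosomal protein and oxidative phosphorylation lists still passed camera at its preset correlation, while 0 single genes passed. Over these 2 lists vehicle library 2 lay -0.40 from the Nrg-1β1 mean, within the largest deviation of 0.58, but the deep vehicle library 1 lay at -0.07 and only vehicle library 3 stood apart, at -1.23.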
